A study of Arabidopsis thaliana with 10 samples.

How the data were processed

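Leaf RNA of Arabidopsis thaliana (accession Col-0) was measured on nylon filters that carried 3292 gene-sequence tags, with radioactively labelled cDNA made from 25 to 30 µg of total RNA and a primer mix for 1827 genes, per the labels' protocols. Plants were grown on soil for 21 days under white light with 8 h of light and 16 h of dark, acclimated for 3 days to light that favours 1 photosystem, and then moved to light that favours the other. Each sample was a pool of 250 to 500 plants, and 3 independent experiments were made per time point. The table used here has 1 column for each of 10 conditions, and how the 3 experiments were combined into it is not given in the sources used here.

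The deposited values are linear ratios per spot, per the labels of a condition to a reference, and their signals, background correction and scaling are not given in the sources used here. The direction of the ratio is not stated either. It was taken as likely that the named condition stands over the plants sampled before the shift, because the sample descriptions speak of expression relative to a reference and the design text places the reference sampling before each shift. The sample titles have the form PSI_vs_PSII, read here as the light before and the light after the shift. Read as a ratio instead, that order would place the reference over the condition. What the white light columns are set against is not stated. If the ratio runs the other way, every "higher" and "lower" turns round.

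The table held 3262 spots, and 34 of them were at 0 in all 10 columns. An exact 0 can be a failed estimate and has no logarithm, so a spot at 0 was treated as having no value in that column. Gene names came from the platform annotation, which is old, with symbols updated through gene identifiers in the TAIR10.1 gene table. Of the spots, 645 were paired with exactly 1 gene, 829 with several genes and 1788 with none. The gene table held the identifiers of 643 of the 645, and the other 2 kept their annotated name. Only spots with exactly 1 gene were named. The 2 spots of the gene that had more than 1 were averaged, which left 3261 features. There were 3 pairs of spots with identical values in every column, and each spot of such a pair was kept as its own feature. The files name no genome build, so no coordinates are given.

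Ratios were analysed on the log2 scale as deposited. Column medians lay between 0.588 and 1.26 instead of 1, so gene values are given relative to the median of their column, that is as the log2 ratio minus the column's median log2 ratio, and counts are given both ways. With 1 column per condition there is no replicate error, and no p-value, SD or interval over experiments was computed. A feature was counted as changed at 2-fold or more. Columns were compared by Pearson's r of log2 ratios across features, with 95% intervals from 500 bootstrap resamples of the features. Such intervals cover only which features were spotted, since genes are not replicates. The time points of a shift share their reference, so unchanged samples against a shared reference were simulated in 100 draws, with equal error in each sample. The number of arrays limits the precision, and the signal over background is unknown because only ratios were used.

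Most genes named in the text were chosen by a rule written before the data were examined. For each shift it took the 8 genes with the highest and the 8 with the lowest mean log2 ratio over the 4 time points, among genes with the same sign at all 4. For each column it took the 3 highest and the 3 lowest genes, and for each fixed list up to 4 members with the largest change past 2-fold. The kinases STN7, STN8 and CSK were to be reported in any case, but no spot was paired with any of them alone. Named in this way were 68 genes. Outside the rule, and after their values were seen, PSBY, PRK and AT1G74470 were named as further measured members of fixed lists, and NdhS, NdhN, CRR21, CRR41, PIFI, AT5G55580, OTP70, OTP85, PAC, ATAB2, SRX and CCS as members of lists drawn up later. The 22 gene lists of 320 genes were also fixed beforehand, 16 of those genes were measured, and 14 lists had no measured gene. A list with at least 5 measured members was set against 10000 random lists of the same size drawn from the named genes, unmatched because ratios carry no level. Another 4 lists were drawn up after the values were in hand.

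Alternatives fixed beforehand were centring each column on its median, quantile normalization, thresholds of 1.5-fold and 3-fold, only genes with a value in all 10 columns, every spot on its own, a pseudocount of 0.432 at the 5th percentile of the positive ratios, list means and lists without their farthest member, Spearman's rho, correlations without the 1% most extreme genes, and each time point left out in turn. A filter on low levels was also planned and could not be made, because ratios hold no levels. The steps were tested on simulated data of 3262 spots with a shared reference, column offsets and 200 genes changed 4-fold in the columns of the shift to PSII light. In those columns 100% of the raised and 100% of the lowered genes passed 2-fold after centring, beside 0.0417% of 3061 unchanged features. The simulated log2 error was 0.2 per sample, so a 4-fold change was all but certain to pass. These shares check the steps only and give no error rate for the deposited columns, whose error is unknown. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.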

Results

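Transcript ratios were recorded in Arabidopsis leaves during 2 opposite changes of light quality. In the first, plants acclimated to light that mainly excites photosystem I (PSI light) were moved to light that mainly excites photosystem II (PSII light). The second shift ran from PSII light to PSI light. Such shifts change the redox state of the electron carriers between the photosystems, and the series asks how gene expression responds to that change. Each shift was sampled at 30 min, 2 h, 8 h and 48 h, and each has a further column for plants in white light, which gives 10 columns with 1 value per spot and no replicate columns. No error can therefore be attached to any ratio below, and no difference between columns could be tested against a spread between experiments. Between 3000 and 3163 of 3261 features had a ratio above 0 in a column. Ratios were read as the named condition over the plants sampled before the shift. This direction is likely from the design text but not stated in the labels. Sample titles of the form PSI_vs_PSII would run the other way if read as ratios. All directions below turn round if the direction used here is wrong. The direction is least settled for the 2 h and 48 h columns of the shift to PSI light, which correlate negatively with some other columns of that shift, and every sign at those times turns if these columns alone are inverted.

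The shift to PSII light gave the largest number of changed features, higher and lower together, at 48 h. After division by the column median, 408 features were 2-fold or more higher and 99 lower there, among them AT1G51350 at 11.3 times the column median, and XERICO, which encodes a RING-type protein linked to abscisic acid, at 6.06 times. At 30 min, 2 h and 8 h the centred counts were 117, 202 and 68 higher and 53, 85 and 60 lower. The white light column of this shift had 256 higher and 166 lower. As deposited, the counts of this shift were 60 higher and 115 lower at 30 min, 167 and 113 at 2 h, 115 and 35 at 8 h, 123 and 1047 at 48 h, and 151 and 409 in white light. The 48 h column had a median ratio of 0.588, and most of its 1047 lower features lay less than 2-fold below that median.

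The shift to PSI light gave centred counts of 145 higher and 37 lower at 30 min, 9 and 65 at 2 h, 244 and 112 at 8 h, and 148 and 231 at 48 h. Its white light column had 59 higher and 16 lower. LHB1B2, a light-harvesting chlorophyll-binding protein of photosystem II, lay at 0.0924 times the column median at 48 h, and AT3G50180 lay at 14.7 times the median at 8 h. As deposited, 32 features were higher and 169 lower at 30 min, 12 and 45 at 2 h, 98 and 572 at 8 h, 366 and 148 at 48 h, and 36 and 39 in white light. Among the higher and lower features together, the higher share at 48 h was 71.2% as deposited and 39.1% after centring, so the prevailing direction in that column depends on where its centre is placed. With the ratio of that column inverted the shares are 28.8% and 60.9%. Centring also turned the prevailing direction in all other columns except 2 h and 8 h of PSII light and 2 h of PSI light. At 48 h of PSII light, for example, the higher share went from 10.5% to 80.5%. All these shares leave out spots at 0. The 48 h column of PSII light had 261 of them, the most of any column, against 98 at 48 h of PSI light. Counted as lower, such spots would reduce the higher share.

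**Figure D1:**
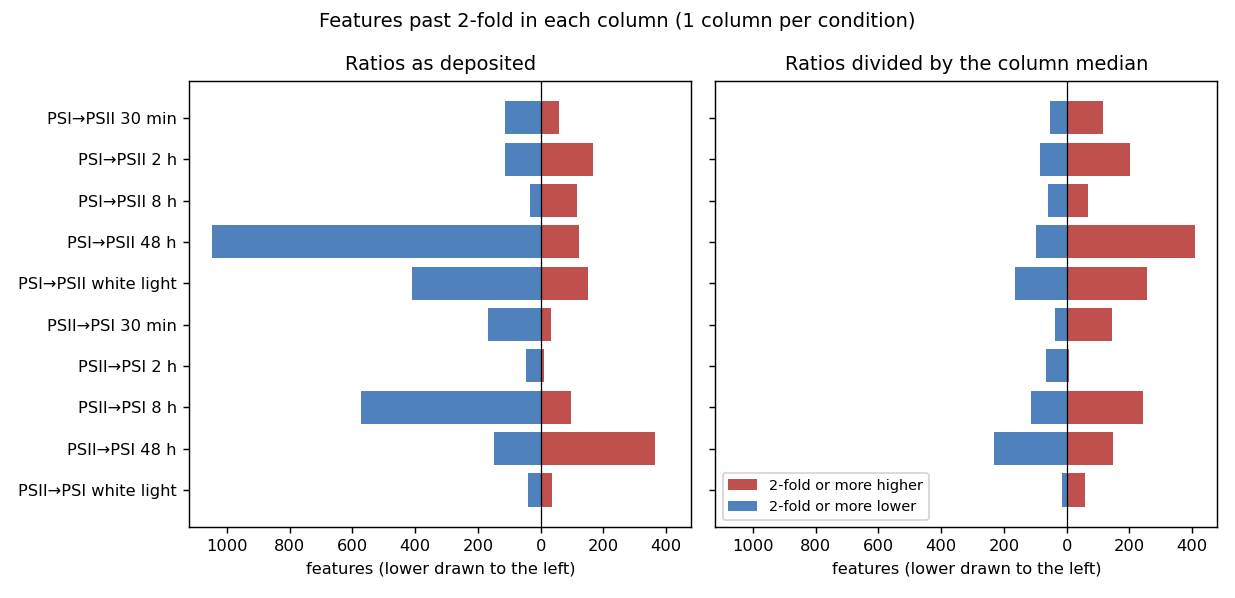
Bars show how many features (x axis) were 2-fold or more higher or lower in each of the 10 columns (y axis), on the left for ratios as deposited and on the right after division by the column median, with 1 value per feature and no error. The 1047 lower features of the 48 h column of the shift to PSII light become 99 after centring.

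Among genes chosen for having the same sign at all 4 time points of the shift to PSII light, AT1G51350 had the highest mean log2 ratio, with 2.51, 2.85, 1.65 and 3.50 above the column median from 30 min to 48 h. XERICO followed with 1.65, 1.82, 1.28 and 2.60, and DI21, a gene known from drought-treated plants, with 1.44, 1.89, 0.95 and 2.26. The other genes among the 8 highest were AT3G52070, AT4G39690, AT4G38040, AT4G16410 and AT2G46300, whose means over the 4 time points lay between 1.45 and 1.60 above the median. The 8 lowest were led by AT4G31930, with log2 values from −1.65 to −1.20 and a mean of −1.40, and AT3G09080, with values from −1.94 to −0.86 and a mean of −1.32. The remaining 6 were AT1G07460, AT4G22650, AT1G11820, AT3G43610, the protein kinase gene ATSIK and AT1G35210, with means from −1.07 to −0.77. Not all of these were far from the median at each time, with −0.32 for AT4G22650 at 8 h and −0.25 for ATSIK at 48 h.

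Counted over all features with a value at each of the 4 time points, 40 of 2949 were 2-fold or more higher at all 4 as deposited and 7 were lower. Multiplying the shares of the separate columns gives 0.00491 and 0.00689, but the columns share a reference, so an excess over these numbers needs no shared response. Of the 40, 5 were spots of a single gene, namely AT1G51350, XERICO, DI21, AT4G16410 and AT4G39690, and of the 7, 2 were, namely AT3G09080 and AT4G31930. The counts were 47 higher and 2 lower after centring. Single genes among the higher were then AT1G51350, XERICO, AT2G46300, AT3G52070, AT4G38040 and AT4G39690, and among the lower only AT4G31930. Without the 30 min column 77 features were higher and 11 lower, and without the 8 h column 26 were lower.

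Single time points of this shift brought out further genes. At 2 h, AT3G03890 and AT1G01080 were lowest, with log2 values of −2.57 and −1.88, and AT3G03890 was listed at 0 in 7 of the other columns. At 8 h, AT-HF, an enzyme of histidine synthesis, was among the 3 highest with a log2 value of 1.29, while AT5G27860 and AT3G08000 lay at −1.66 and −1.49. At 48 h, AT4G32060 was the third highest at 4.93 times the median, and AT3G52550 and AT2G23160 were lowest with −2.73 and −2.21. For both of the latter, the values at 30 min, 2 h and 8 h lay between −0.34 and 0.06.

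**Figure D2:**
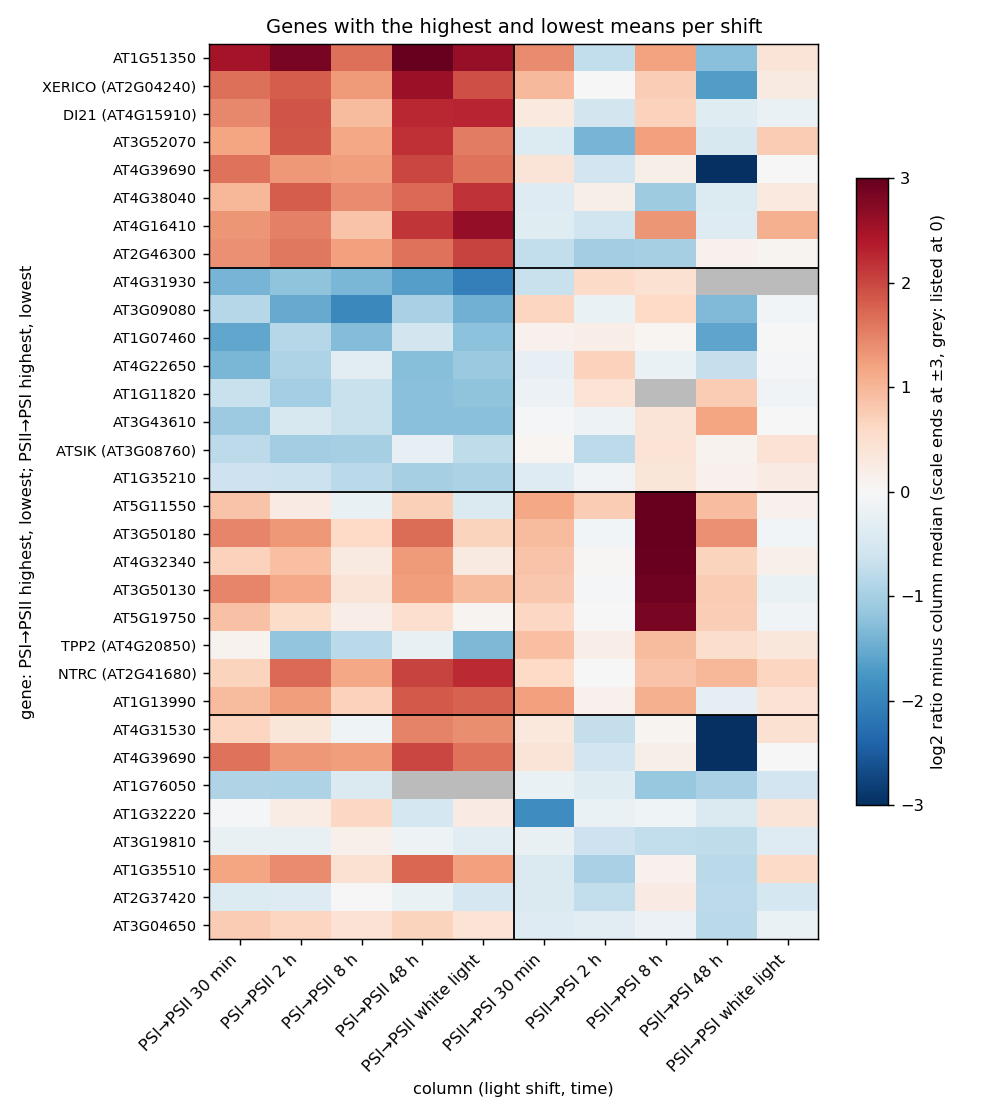
Colours give the log2 ratio minus the column median for the 8 highest and 8 lowest genes of each shift (y axis, in 4 blocks) in the 10 columns (x axis), with grey for ratios listed at 0 and 1 value per cell. The genes were ranked among those with the same sign at all 4 time points as deposited. Genes of the upper block, such as AT1G51350 and XERICO, were high in every column of the shift to PSII light, whereas 5 of the 8 in the third block were high mainly at 8 h of the shift to PSI light.

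After the shift to PSI light no feature passed 2-fold in the same direction at all 4 time points, as deposited or centred, among 2988 with values at all 4, and after quantile normalization 1 was lower. Leaving out the 2 h column gave 1 higher and 1 lower, and leaving out the 48 h column gave 3 lower. Without both of these columns 11 features were higher and 68 lower, and with the ratio inverted in both, after centring, 5 were higher at all 4. Only 15 genes with a spot of their own were above 0 at all 4 time points as deposited, against 80 in the shift to PSII light. Of these 15, the 5 with the highest means owed them mainly to the 8 h column. There, AT3G50180 reached a log2 value of 3.88, AT5G11550 3.33, AT4G32340 2.97, AT3G50130 2.92 and AT5G19750 2.86, while at the other 3 time points these 5 genes lay between −0.07 and 1.37. The other 3 of the 8 highest were TPP2, which encodes tripeptidyl peptidase II, with a mean of 0.65, NTRC with 0.61 and AT1G13990 with 0.54.

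Below 0 at all 4 time points of this shift as deposited were 29 genes with a spot of their own, against 102 in the shift to PSII light. The 8 lowest of the 29 were AT4G31530, AT4G39690, AT1G76050, AT1G32220, AT3G19810, AT1G35510, AT2G37420 and AT3G04650, with means from −0.90 to −0.42. Relative to the median some of them were above it at a time point, such as AT2G37420 with 0.23 at 8 h. This ranking rests on the direction of the 2 h and 48 h columns: with both inverted, the means of AT4G31530 and AT4G39690 become 1.11 and 1.15, and those of the other 6 lie between −0.34 and 0.37. The 8 highest keep means above 0 with both inverted, between 0.11 and 0.88. For AT4G31530 and AT4G39690 the 48 h column dominated, with −3.30 and −3.46, against values from −0.71 to 0.38 at the earlier time points. For AT1G32220 the 30 min column did, with −1.86. At 30 min the highest genes were AT1G51350, AT3G09850 and AT3G22690, at 2.68, 2.64 and 2.63 times the median, and AT4G18180 was among the 3 lowest with a log2 value of −1.63. At 2 h, AT5G49590, AT2G26340 and AT4G12270 were highest with 2.00, 1.91 and 1.22, and AT3G09850, AT4G20690 and AT2G36480 lowest with −2.39, −1.48 and −1.41. At 8 h, AT2G36480, AT1G01080 and AT2G26340 were lowest with −2.54, −2.45 and −2.30, so that AT2G26340 lay on opposite sides of the median at 2 h and 8 h. At 48 h, AT1G02020 was highest with 3.65, that is 12.6 times the median, followed by AT4G37230 with 2.26 and AT2G48090 with 1.86.

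The 48 h columns of the shifts place photosystem genes on opposite sides of the median as read here, and on the same side if the column of the shift to PSI light is inverted. PSBW and PSBY, small subunits of photosystem II, were 2.28 and 2.65 times the column median at 48 h of PSII light. At 48 h of PSI light PSBW was at 0.128 times the median and PSBY had a log2 value of −0.74. PSAN, a subunit of photosystem I, had log2 values of 0.94 and −1.31 in the same columns. As deposited, PSBW, PSBY and PSAN had log2 values of 0.42, 0.64 and 0.17 at 48 h of PSII light, all under 2-fold. At 48 h of PSI light they had −2.63, −0.40 and −0.98 as deposited. LHB1B2 had 0.08 at 48 h of PSII light relative to the median and −0.68 as deposited, after −1.47 at 2 h and −1.38 at 8 h, and it had the second lowest named value at 48 h of PSI light, with −3.44. At 30 min of PSI light all 4 of these genes were above the median, and as deposited their log2 values were 0.37 for PSBW, 0.63 for PSBY, 0.74 for LHB1B2 and 0.45 for PSAN.

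Of the Calvin-Benson cycle, SBPASE, which encodes sedoheptulose-bisphosphatase, and PRK, which encodes phosphoribulokinase, were measured. SBPASE had −1.79 at 30 min, −1.55 at 8 h and 1.18 at 48 h of PSI light, and was listed at 0 at 48 h of PSII light. PRK stayed under 2-fold in every column, with log2 values from −0.48 to 0.60 relative to the median. Of the chlorophyll synthesis genes, CHLM, the magnesium-protoporphyrin methyltransferase, stayed between −0.77 and 0.26 relative to the median, and as deposited had −1.10 in white light and −0.98 at 48 h of the shift to PSII light. AT1G74470, which encodes geranylgeranyl reductase, had 1.41 at 48 h of PSII light and was at 2.11 and 2.46 times the median at 30 min and 8 h of PSI light.

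NTRC, the NADPH-dependent thioredoxin reductase of the chloroplast, was above the median in all 10 columns as read here. After quantile normalization it had −0.17 at 2 h of PSI light, still above the median of that scale, which lies below 0. Its log2 values after the shift to PSII light were 0.67, 1.69, 1.15 and 2.03, and after the shift to PSI light they were 0.59, 0.01, 0.86 and 1.00. With the 2 h and 48 h columns of PSI light inverted, NTRC lies below the median in both, and its mean over that shift is 0.11. The other measured gene of the thioredoxin list, AT2G04700, a ferredoxin-thioredoxin reductase subunit, lay between −0.81 and −0.28 at the time points of PSII light and at 0.61, 0.44, 1.23 and −0.94 from 30 min to 48 h of PSI light, and as deposited it had −1.05 at 48 h of PSII light. The single measured gene of the fixed antioxidant list, AT3G52960, which encodes a peroxiredoxin, stayed under 2-fold relative to the median, between −0.62 and 0.92, and as deposited had −1.02 at 30 min of PSI light.

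**Figure D3:**
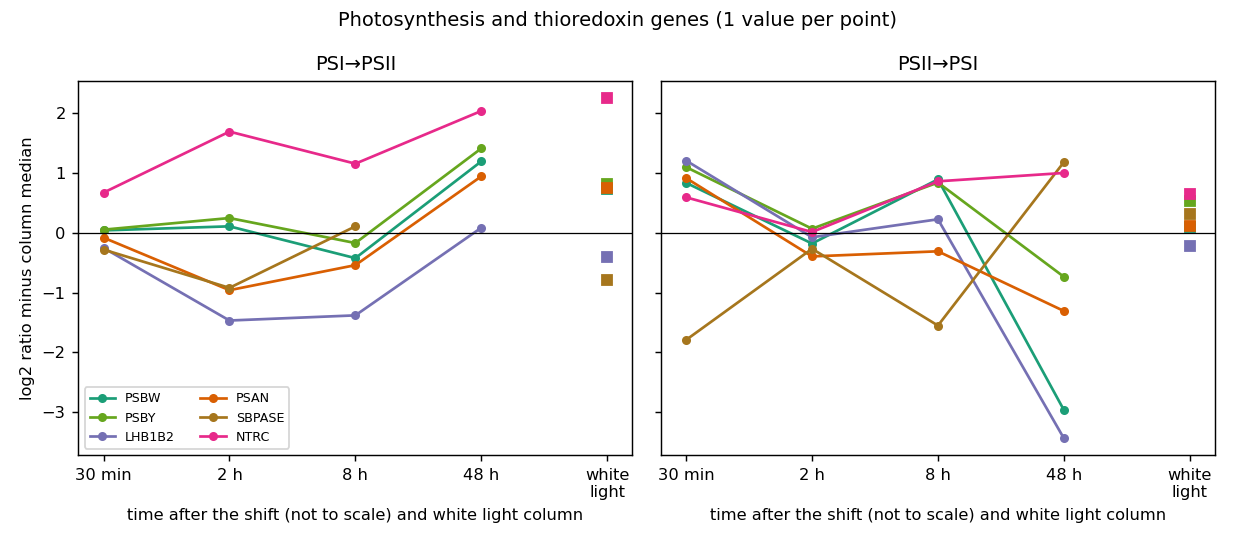
The log2 ratio minus the column median (y axis) is drawn for 6 genes at the 4 time points of each shift (x axis, not to scale) as circles joined by lines, and in white light as squares, with 1 value per point. PSBW and LHB1B2 lie at −2.96 and −3.44 in the 48 h column of the shift to PSI light, and NTRC lies above 0 throughout. Values at 2 h and 48 h of that shift turn sign if those columns are inverted.

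The plastid ribosomal proteins were the only fixed list with 5 measured members. None of its members passed 2-fold relative to the median except AT3G54210, with 1.14 at 48 h of PSI light. As deposited, AT1G29070 and AT1G64510 had −1.34 and −1.33 at 48 h of PSII light. The median of the list lay between −0.16 and 0.17 on the centred scale. The list's median as deposited moved with its columns, from −0.87 at 48 h of PSII light to 0.24 at 2 h of PSI light. Among random lists of the same size its percentile ranged from 24.9 to 85.1 over the 10 columns.

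The 4 time points of the shift to PSII light resembled each other across features, and those of the shift to PSI light did not. Over the 6 pairs of time points Pearson's r ran from 0.529 to 0.815 with a mean of 0.699 for the shift to PSII light. For the shift to PSI light it ran from −0.289 to 0.489 with a mean of 0.00626, and with the ratio inverted in the 2 h and 48 h columns the mean is 0.201. Unchanged samples that share a reference gave a simulated mean of 0.498. These correlations are across genes, which are not independent replicates. Within the shift to PSI light, 30 min and 8 h correlated at 0.489, whereas 48 h correlated with 30 min at −0.289 (bootstrap interval −0.331 to −0.249) and 2 h with 8 h at −0.192 (−0.239 to −0.145).

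The opposite shifts were set against each other at matched times to see whether one mirrored the other. Across features r was 0.256 at 30 min, −0.250 at 2 h, 0.0485 at 8 h and −0.287 at 48 h, the last with a bootstrap interval of −0.320 to −0.244. The sign at 2 h and 48 h rests on all columns having the same ratio direction, which the correlations within the shift to PSI light leave less settled for its 2 h and 48 h columns. Over all 25 pairs of columns across the shifts r ran from −0.299 to 0.542, and 10 were negative. The highest was for 48 h of PSII light with 8 h of PSI light, and 48 h of PSII light with 30 min of PSI light had 0.465. At 48 h, 110 features were 2-fold or more above the median in PSII light and 2-fold or more below it in PSI light, against 30.5 for independent columns. They included 16 spots of a single gene, with PSBW, XERICO, AT1G51350, AT3G09850, AT4G31530 and AT4G39690 among them. Features above in both 48 h columns numbered 8, against 16.8 for independent columns, and 6 were below in PSII light and above in PSI light, against 3.86. As deposited, 26 features were higher in PSII light and lower in PSI light (5.93 for independent columns) and 118 the other way round (110 for independent columns). At 30 min, by contrast, 30 features were 2-fold or more above the median in both shifts, against 5.25 for independent columns, and 4 were below in both, against 0.466. None was above in PSII light and below in PSI light, against 1.25, and 4 were the other way round, against 1.96. As deposited the counts at 30 min were 4 higher in both (0.611 for independent columns), 12 lower in both (5.39), 2 higher in PSII light and lower in PSI light (3.17) and 2 the other way round (1.04). These shifts have different references, and the counts are of the direction relative to the column median.

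**Figure D4:**
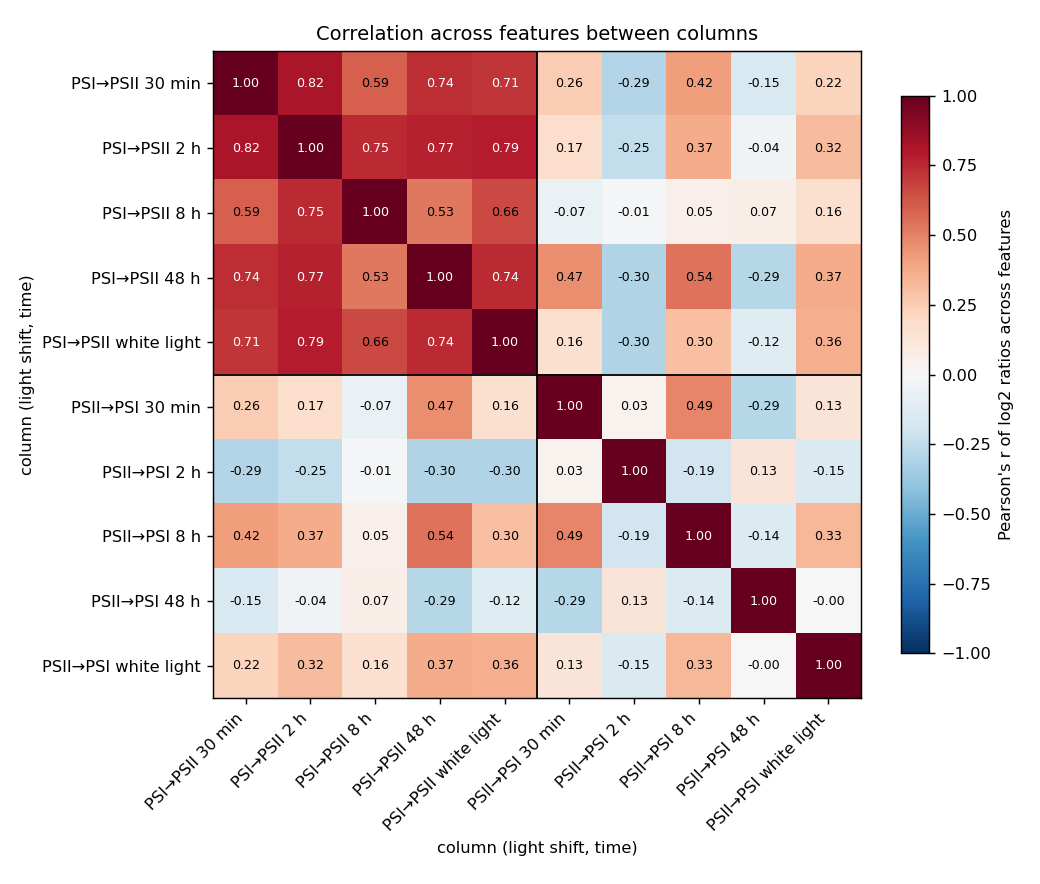
Each cell gives Pearson's r of log2 ratios across features between 2 of the 10 columns (both axes), with the columns of the shift to PSII light first. The pairs of the shift to PSII light lie between 0.529 and 0.815 and those of the time points of the shift to PSI light between −0.289 and 0.489.

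The white light column filed with the shift to PSII light correlated with the 4 time points at 0.662 to 0.787, and 208 features were 2-fold or more above the median both there and at 48 h. If that column shares the reference of the time points, this by itself raises both figures. The highest genes in white light were AT4G16410, AT1G51350 and DI21, with 2.63, 2.62 and 2.28, and the lowest were AT4G31930, AT5G66780 and AT2G01400, with −2.05, −2.05 and −1.96. NTRC had 2.25. The white light column of the shift to PSI light correlated with its time points at −0.147 to 0.328, and its highest genes were AT2G04540, AT1G49850 and CBL, which encodes cystathionine beta-lyase, with 1.21, 1.15 and 1.12. Its lowest were AT5G06930, AT3G15490 and AT1G01250, with −0.96, −0.95 and −0.85. The white light columns of the shifts correlated with each other at 0.364. What the white light plants are set against is not stated in the labels.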

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

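Apart from the correlations without the most extreme genes, the tests in this part were chosen after the result in question had been seen. Among the named genes, AT3G04650 lay above the column median at all 4 time points of the shift to PSII light (log2 0.44 to 0.75) and below it at all 4 of the shift to PSI light (−0.80 to −0.19), a mean difference of 1.04. CHLM (AT4G25080) lay below the median throughout the former (−0.50 to −0.22) and above it throughout the latter (0.16 to 0.26), a mean difference of −0.53. The differences were not tested, since each time point has 1 value. As deposited, AT3G04650 was above 0 at 3 of the 4 time points of PSII light and CHLM below 0 at 2 of the 4 of PSI light. After quantile normalization CHLM had −0.06 and −0.04 at 8 h and 48 h of PSI light, still above the median of that scale, which lies below 0. Over 2839 features with all 8 values, 33 and 38 showed these opposed patterns, against 39.9 and 42.7 for independent shifts, so such genes were no more frequent than that. This reading needs the 2 h and 48 h columns of PSI light to run as the others: with both inverted, neither gene keeps a single sign in PSI light, and the counts are 30 and 20, against 87.0 and 90.2.

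In the shift to PSI light, 3 pairs of time points correlated negatively although all share a reference, namely 48 h with 30 min and with 8 h, and 2 h with 8 h, whereas 2 h with 30 min had an r of 0.0317 (bootstrap interval −0.0168 to 0.0768). A distortion of the ratio scale that keeps the order of spots is argued against, because the highest Spearman's rho of the 3 negative pairs was −0.146 (bootstrap interval −0.185 to −0.110), and so are a few extreme spots, with a highest r of −0.172 (−0.212 to −0.131) once the 1% most extreme genes were left out. An inverted ratio in the 2 h and 48 h columns stays open. Spots at 0 in 1 of them alone had a median of 0.622 (0.206 to 0.868, 21 spots) in the other 3 columns of the shift. Those at 0 in 1 of these 3 alone had −0.141 (−0.231 to −0.0368, 118 spots), taken over the rest of these 3 columns. A median above 0, the first yardstick, would have spoken for inversion, but the lowest 1% of spots above 0 had 0.625, so the negative correlation alone gives that value and the test, whose yardstick was then changed, cannot decide. A response to PSI light that differs between the time points is a biological alternative that was not tested.

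The columns of the shift to PSII light, white light included, resembled each other. Error of the shared reference would add the same covariance to each of the 6 pairs of time points, whereas the covariance ranged from 0.125 for 30 min with 8 h to 0.356 for 2 h with 48 h, a difference of 0.231 (bootstrap interval 0.212 to 0.253, against at most 0.0378 from resampling alone had all pairs 1 covariance), and over the 10 pairs with white light, whose reference is not stated, 0.295 (0.271 to 0.319). Such an error of a single size on a common log2 scale is therefore argued against as the whole of the shared signal, but it stays open as a part of it, as does a different scale per column. Without the 1% most extreme genes the mean r of the 10 pairs was 0.701 (0.680 to 0.716). With all genes the mean was 0.699 for the 6 pairs of time points and 0.727 for the 4 with white light. Extreme spots were therefore not the source of the shared signal. The trimmed mean also lay above the simulated 0.498, but that value holds only for equal error in reference and samples and cannot test a shared reference. A lasting difference between PSI light plants and all others is a biological alternative that was not tested.

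In the 8 h column of the shift to PSI light, 55 spots were 4-fold or more above the median, 5 of them spots of a single gene (AT3G50180, AT3G50130, AT5G19750, AT5G11550 and AT4G32340). None of them was so in the other 4 columns of that shift, and their median there lay between −0.06 and 0.49. Those columns held few such spots at all, namely 7 at 30 min, 1 at 2 h, 7 at 48 h and 4 in white light. The lack of overlap therefore says little. In the shift to PSII light the 55 included 9 of 81 such spots at 48 h and 6 of 22 at 2 h. They also included 3 of 43 in white light and 2 of 7 at 30 min. The medians of the 55 in these columns were 0.74, 0.53, 0.15 and 0.66. At 8 h of the shift to PSII light the 55 included neither of 2 such spots, and their median was 0.14. Uneven hybridisation over spots with neighbouring numbers cannot be told from other sources: of 71 such neighbours 8.45% (exact binomial interval 3.16 to 17.5) were 2-fold or more above the median, against 6.14% of all other spots, and the layout of the filter was not used here. Weak signal stays open too, since 7.27% of the 55 (2.02 to 17.6) were listed at 0 in some other column, against 10.4% of all others. A transient response at 8 h was not tested.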

How the results depend on the processing

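The alternatives that centre or quantile-normalize the counts over several time points, invert the 2 h and 48 h columns of the shift to PSI light (gene means included) or leave both out were chosen after seeing the data. Counts are given here in the order 30 min, 2 h, 8 h, 48 h and white light, first for the shift to PSII light and then for the shift to PSI light, and only where they left 1.5 times the main count. Centring moved 16 of 20 counts: none at 2 h, higher 117, 68, 408 and 256, then 145, 244, 148 and 59, and lower 53, 60, 99 and 166, then 37, 112, 231 and 16. Its cause is the column medians, which centring sets to a ratio of 1. Quantile normalization moved 13, namely higher 97, 97 and 95 (30 min, 2 h, white light), then 97, 99, 99 and 98 (without 8 h), and lower 153, 146 and 148 (8 h, 48 h, white light), then 154, 151 and 153 (2 h, 8 h, white light), since it gives all columns 1 distribution. By construction the thresholds moved all 20: at 1.5-fold higher 209, 379, 414, 247, 307, then 121, 169, 192, 1018, 128, and lower 629, 442, 111, 1798, 1016, then 1131, 114, 1454, 275, 376, and at 3-fold higher 9, 52, 21, 32, 52, then 7, 2, 47, 82, 6, and lower 14, 19, 10, 184, 84, then 31, 15, 102, 51, 2. The pseudocount, which shrinks ratios and counts spots at 0 as lower, moved 15: higher 25, 90, 58, 73, 91, then 14, 5, 172 and 12 (without 8 h), and lower 118, 346 and 266 (8 h, 48 h, white light), then 111, 225 and 116 (2 h, 8 h, white light). Genes with a value in all 10 columns gave other counts for lower at 30 min, 2 h and 8 h of PSII light (52, 66 and 20) and higher at 2 h of PSI light (4), with fewer genes counted. Every spot on its own moved none of the 20.

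The median of the plastid ribosomal list moved by more than the SD of its members under centring to 0.11 at 30 min and −0.10 at 48 h of PSII light, and to 0.16, 0.0785 and −0.13 at 30 min, 2 h and 8 h of PSI light, and under quantile normalization to −0.31 and −0.26 at 8 h and 48 h of PSII light and −0.0138, −0.0485 and −0.30 at 30 min, 2 h and 8 h of PSI light, as the columns' medians shift. By less than that SD, but with a change of sign, it went under centring from 0.12 to −0.09 at 8 h of PSII light, from −0.16 to 0.17 in white light of that shift and from 0.17 to −0.16 at 48 h of PSI light, the last also under quantile normalization (−0.32). List means, lists without their farthest member, complete genes and single spots moved none of its 10 medians by more than that SD. Correlations kept their value within the bootstrap interval with complete genes in 9 of 9 cases, and centring cannot alter them. Spearman's rho gave −0.314 and −0.213 between the shifts at 2 h and 48 h, means of 0.643 for the time points and 0.694 for white light in the shift to PSII light, and 0.0964 for white light in the shift to PSI light. Quantile normalization gave −0.232 between the shifts at 48 h, and leaving out the 1% most extreme genes gave a mean of 0.679 for the time points of PSII light, and the cause was not tested. Inverting the ratio in the 2 h and 48 h columns of PSI light turns the sign between the shifts by construction, to 0.250 at 2 h and 0.287 at 48 h, and gives means of 0.201 for the time points and 0.151 for white light in that shift.

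Among counts at all 4 time points, leaving out 1 time point gave 40 to 77 higher and 8 to 26 lower in the shift to PSII light, and 0 to 1 higher and 0 to 3 lower in the shift to PSI light, where fewer columns must pass. At 1.5-fold they were 126 higher and 30 lower, then 1 and 3. Lower in the shift to PSII light were 2 features after centring and 3 after quantile normalization, and 1 in the shift to PSI light after quantile normalization. With the 2 h and 48 h columns inverted and centred, 5 features of the shift to PSI light were higher, and without those columns together 11 were higher and 68 lower. None of the 103 gene values that the naming rule ranked changed sign under centring or quantile normalization. The rule took extremes and means of genes with a single sign, and centring moved no value by more than 0.77. Unchanged signs were therefore likely from the start. Quantile normalization moved 10 of the 103 by over 1 log2 unit from the value relative to the median, at most by 1.62 (AT3G50180 at 8 h of PSI light, to 2.26). With the 2 h and 48 h columns of PSI light inverted, 7 of the 8 lowest means of that shift turned sign, among them those of AT4G31530 from −0.90 to 1.11 and AT4G39690 from −0.87 to 1.15, with AT1G32220 (−0.34) the exception. The filter on low levels was not run, because ratios hold no levels, and so signal over background could not be judged. No paired analysis was possible because no replicate columns exist.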

Other observations

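The tests and lists of this part were all chosen after values had been seen. Signs at 2 h and 48 h of PSI light turn if those columns are inverted. Of the chloroplast NADH dehydrogenase-like complex and its factors, NdhS was above the median at each time point of PSII light, with log2 values of 0.99, 1.14, 0.55 and 2.26, and below it at 48 h of PSI light, with −0.67 as deposited, whereas NdhN, CRR21, CRR41 and PIFI stayed under 2-fold relative to the median in every column (CRR21 had −1.11 as deposited at 48 h of PSII light). The median of these 5 genes lay between the percentiles 22.3 and 71.0 of random lists in all 10 columns. Of 6 organelle RNA processing and translation genes, AT5G55580 (mTERF9) had 1.11, 1.38, 0.69 and 1.68 and OTP70 had 0.58, 1.01, 0.54 and 0.92 in PSII light, while PAC, OTP85, CRR21 and ATAB2 stayed under 2-fold relative to the median in every column where they had a value (as deposited ATAB2 had −1.31 at 48 h of PSII light). At 48 h of PSI light 5 of the 6 were below the median, the list's median was −0.51 and its percentile 2.50. In the other columns its percentile ranged from 21.9 to 93.4.

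Of 6 thiol redox and antioxidant genes, the median was 0.77 at 8 h of PSI light, at the 99.8th percentile, with NTRC and AT2G04700 at 0.86 and 1.23, and 2 of the 6 below the median, among them SRX, which encodes sulfiredoxin, with −0.95. In the other columns the list's percentile ranged from 16.0 to 98.4. CCS, the copper chaperone of superoxide dismutase, had −1.36 in the white light column of the shift to PSII light. The 8 measured photosynthesis genes, merged into a list, had a median of −0.49 at 2 h and 0.94 at 48 h of PSII light, at percentiles 0.650 and 99.3, the latter over 7 genes. In PSI light their median was 0.87 at 30 min, at percentile 100, and −0.66 at 48 h (percentile 0.320). In the other 6 columns it lay between −0.22 and 0.38, at percentiles from 3.24 to 96.0. These genes had been seen before they were merged, so the percentiles only describe them.

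A hypothesis from the design is that transcripts of photosystem I and photosystem II move in opposite directions, since each light is unbalanced for the other photosystem. PSAN and the median of PSBW, PSBY and LHB1B2 had opposite signs in 3 of the 8 columns of the time courses relative to the median. These were 30 min (−0.08 and 0.04) and 2 h (−0.96 and 0.11) of PSII light and 8 h of PSI light (−0.31 and 0.84). The values at 30 min lay close to 0, and at 2 h LHB1B2, with −1.47, was on the side of PSAN. As deposited the signs were also opposite in 3 of 8 columns, with 2 h of PSI light (−0.23 and 0.09) in place of 30 min of PSII light (−0.31 and −0.19). The median of the 3 genes at 2 h of PSII light was then 0.007. At 48 h they moved together in both shifts, with 0.94 and 1.19 in PSII light and −1.31 and −2.96 in PSI light. With a single gene of photosystem I the hypothesis cannot be decided.

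Column centre and shape went together. All 7 columns with a median under 1 had a positive skew of their log2 ratios, and all 3 with a median above 1, namely 8 h of PSII light and 2 h and 48 h of PSI light, had a negative skew, of −0.0955, −1.80 and −0.840. The first of these is small, and the ratio direction of the 2 h and 48 h columns of PSI light is not settled.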
